A study of Rattus norvegicus with 6 samples.

How the data were processed

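Total RNA from the kidneys of 6 male rats was measured on Affymetrix Rat Expression 230 2.0 arrays, 1 array per animal, per the labels' protocols. The deposited table holds log2 probe set intensities already on a scale comparable between arrays, judged from the values: they run from 3.76 to 15.1 and array medians differ by little. The software and the method that made them are not given in the sources used here. Per the series' design text, the submitters adjusted p-values by the Benjamini-Hochberg method in R 2.8.1. Scanner files were not used here.

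The columns were matched to samples by the labels, and groups and rat numbers were taken from the sample titles. No 2 arrays held identical values, and the correlation between arrays lay between 0.985 and 0.998. The table has 31099 probe sets, of which 57 Affymetrix control probe sets were left out of the tests. Probe sets were named through the platform annotation, with symbols updated by Entrez identifier to the RefSeq gene table of the GRCr8 rat assembly. Of the 31042 tested, 20826 had 1 gene symbol, 436 had several and were not named, and 9780 were not listed and stay unnamed. Of those with 1 symbol 20758 matched the gene table, and 14217 genes had a probe set. The table names no genome build, so the assembly was used for names, chromosomes and neighbouring genes only, and no coordinates are given.

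Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, two-sided, Benjamini-Hochberg, adjusted p under 0.05). The residual degrees of freedom were 4, and 8.49 with the prior. For gene-level results the probe set with the highest mean over all arrays stood for its gene. Of 37 gene lists, 36 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. The juxtaglomerular list had 4 measured genes and was not tested. With a preset correlation 13 lists were called, 12 higher and 1 lower, and with an estimated correlation 0 of them. The fry test, which asks whether the genes of a list move on balance one way, called 3 lists, 2 of them among the 13 (tubular injury at adjusted p = 0.0195 and fibroblasts at adjusted p = 0.0180) and the thick ascending limb, which was lower (adjusted p = 0.0412). Among uncalled lists, median, mean and test differed in sign for late proximal tubule, principal cell, endothelium, oxidative phosphorylation, glutathione and NRF2, xenobiotic metabolism, immediate early, action potential, ubiquitin ligase and near-Rffl lists. The share of called genes on chromosome 10 was tested with Fisher's exact test, as was, outside the fixed design, that of each other chromosome. RNA quality was the difference between 3′ and 5′ control probe sets of beta-actin and Gapdh, compared by an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

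The method was tested on simulated data for this comparison, with real probe set means and spreads on 31042 probe sets. It recovered 56.7% of 67 probe sets changed by 0.5 on the log2 scale, 95.5% of 67 changed by 1 and 100% of 66 changed by 2, with 13 false calls. A simulated list shift of 0.4 was called and 0 unmoved lists were. The noise was drawn for each probe set on its own, so genes of a simulated list did not vary together. In the real lists the estimated correlation ran from -0.04 to 0.81. False list calls that come from such correlation were therefore not tested. Each probe set had 1 SD for both groups, although real arrays correlated at 0.992 to 0.996 within S and 0.997 to 0.998 within congenic rats. The recovery and false calls of probe sets therefore hold for equal, independent noise only.

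The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls among called probe sets with 1 symbol and no overlap between groups, with each gene taken by its probe set with the smallest p. It adds Rffl and listed genes near it with an unadjusted p under 0.05, up to 3 members of each other list with the smallest p, and the 2 most abundant markers of each called cell type list. Slc4a4, Slc31a1, Snhg11, Nphs1, Wt1, Calb1, Slc12a3, Mbd2, Stard6, C18h18orf54, Rab27b, Dcc, Igfbp3, Mfap4, Osgin1, RT1-Bb and RT1-Da were chosen after their values were seen.

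Alternatives were quantile normalization, median centring, a filter that dropped probe sets below the percentile 40 of mean intensity, an intensity trend, robust eBayes, an unmoderated test, array weights, the rat number as a block, leaving out each rat in turn, 1 probe set per gene, other list tests, other thresholds, and, chosen after the data were seen, the RNA quality difference as a covariate.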

Results

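Kidney gene expression was measured in 6 male rats, 3 Dahl salt-sensitive (S) controls and 3 congenic S.LEW(10)x12x2x3x5 rats, with 1 Affymetrix array per rat. The S rat is an inbred strain that develops salt-sensitive hypertension and leaks protein into the urine. The congenic strain carries a piece of chromosome 10 from the Lewis (LEW) rat on the S background. All rats were weaned at 30 days, ate a diet with 0.3% salt and were killed at 53 days. Each array held 31099 probe sets, and the median log2 intensity per array lay between 7.47 and 7.50. Array values have no read depth, so the precision rests on the 3 rats per group. The comparison asks which kidney transcripts differ between the strains, in a study concerned with endosomal recycling in the proximal tubule and with proteinuria.

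Transcripts of the proximal tubule transporters Slc5a12, Slc5a2 and Slc22a8 and of the matrix gene Lum were higher in the congenic kidney, and the probe set of Rbp4, the plasma carrier of retinol, was 3.67-fold lower. Of 22 tubular injury genes 10 rose and of 31 matrix and fibrosis genes 7, and both lists were called higher (adjusted p = 1.04e-08 each, limma's camera), but not with an estimated correlation (adjusted p = 0.40 and adjusted p = 0.51). Among called probe sets with 1 gene symbol the largest rise was that of Spp2, a secreted phosphoprotein, from 8.01 ± 0.79 in S to 10.38 ± 0.39 in congenic rats (log2, SD, n = 3; 5.19-fold). Slc5a12, a sodium-coupled lactate transporter, rose 4.85-fold, Slc5a2, the main glucose transporter of the early proximal tubule, 3.18-fold, and Slc22a8, an organic anion transporter, 3.15-fold. The S mean of Slc5a12 was 6.10, near the lower quartile of the S arrays (5.88 to 5.95). No detection call was used, so its exact fold is uncertain. The SDs of Slc5a12, Slc5a2 and Slc22a8 were 0.80, 0.75 and 0.68 in S and 0.46, 0.36 and 0.24 in congenic rats. Kap and Miox, the most abundant early proximal tubule markers, did not pass. Calb1, a distal tubule marker, was at 9.38 in S rat 2, 13.51 in S rat 1 and 13.46 or above in congenic rats. Whether tissue content differed in a way that raised these transporters was not tested. Lum, which encodes the collagen-binding proteoglycan lumican, rose 3.39-fold, with a log2 change of 1.76 ± 0.18 (SE). Rbp4 fell from 8.74 ± 0.20 to 6.86 ± 0.48 (log2, SD, n = 3). With a measure of RNA quality in the model the log2 changes shrank, from 2.38 to 1.39 for Spp2, from 2.28 to 1.33 for Slc5a12, from 1.67 to 0.60 for Slc5a2, from 1.65 to 0.59 for Slc22a8, from 1.76 to 1.25 for Lum and from -1.87 to -1.22 for Rbp4, and none passed.

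Of 31042 probe sets tested, 1862 (6.00%) passed an adjusted p of 0.05, 1078 higher and 784 lower in congenic rats. Of these, 156 were at least 2-fold higher and 6 at least 2-fold lower. With only the brightest probe set of each gene the balance turned, with 301 genes higher and 380 lower. In all 1862 the groups did not overlap, as in 31.2% of all tested probe sets, against 10% by chance. The count depended on single rats: 4752 were called without S rat 1, 968 without S rat 2, 350 without congenic rat 1, 8 without congenic rat 3, and 0 without S rat 3 or without congenic rat 2, where limma gave 6968 and 5575 probe sets below an unadjusted p of 0.05. An unmoderated test per probe set called 0 after adjustment, with 6166 below an unadjusted p of 0.05.

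With each gene taken by its probe set with the smallest p, the other rises among the 12 largest were at Tm9sf3, a membrane protein of the secretory pathway (4.46-fold), App, the amyloid precursor (4.28-fold), Caprin1, an RNA-binding protein (4.0-fold), Plekhb2 (3.54-fold), Ppp3r1, the regulatory subunit of calcineurin (3.38-fold), Msn, which encodes moesin (3.16-fold), and St6gal1, a sialyltransferase (3.15-fold). Each of these 7 genes has a brighter probe set that did not pass. The named probe sets of Tm9sf3 and Caprin1 were dim in S, at 6.10 and 6.09. The brightest other probe set of App had a log2 change of 0.09 at a mean of 13.7, that of Caprin1 0.12, that of Tm9sf3 0.05, that of Plekhb2 0.07, that of Ppp3r1 0.20, that of Msn -0.0019 and that of St6gal1 -0.31, with adjusted p from 0.0574 to 0.99. The second probe set of Slc22a8, a dimmer one, also rose (1.46, adjusted p = 0.0373), and that of Slc5a12 stood at 0.42 (adjusted p = 0.0674). Larger or similar rises fell outside this choice. Slc4a4, a sodium bicarbonate cotransporter of the proximal tubule, rose by 1.94 ± 0.43 (SE, 3.83-fold, adjusted p = 0.0403) at its brighter probe set and by 0.56 at the one with the smaller p. Slc31a1, a copper transporter, rose by 1.66 at one probe set and by 0.69 at another, while its brightest stood at -0.06 (adjusted p = 0.70). In addition, 2 probe sets without a single gene symbol rose by 2.87 and 2.42 (0.29 and -0.11 with the RNA quality term).

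After Rbp4, the largest falls by the same choice were those of Gpha2, a glycoprotein hormone subunit (log2 change -1.03), Cyp1a1, the dioxin-inducible cytochrome P450 (-1.02), Eaf2, a transcription elongation factor (-1.02), Cgref1 (-0.98), LOC100910558 (-0.96) and Sox4, a developmental transcription factor (-0.94). Prrg4 (-0.92), Fxyd6, a regulator of the sodium pump (-0.91 ± 0.08 SE, adjusted p = 0.00596), Cftr, a chloride channel (-0.90), Cox8b, a cytochrome oxidase subunit (-0.84), and Ggct, an enzyme of glutathione turnover (-0.83), followed. The brightest other probe set of Sox4 stood at 0.09 (adjusted p = 0.41) and that of Ggct at -0.31 (adjusted p = 0.0522). Snhg11, a noncoding RNA, fell by 0.87 at a probe set outside this choice and by 0.69 at the one with the smallest p.

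**Figure D1:**
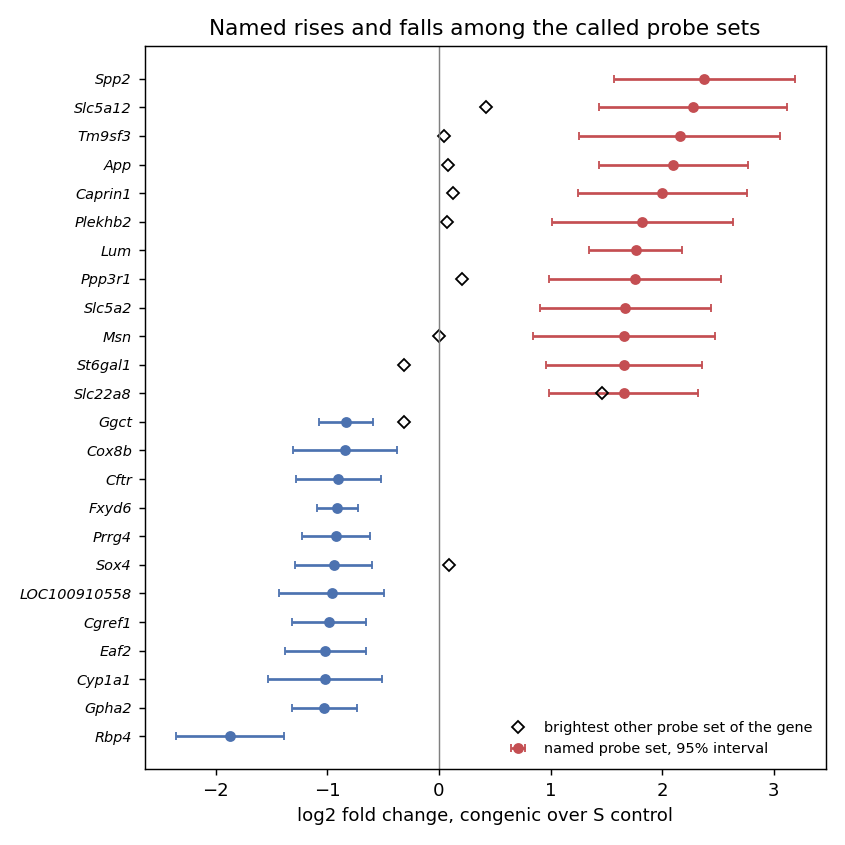
Log2 fold change, congenic over S control, of the 12 largest rises and 12 largest falls among called probe sets with 1 gene symbol, each gene taken by its probe set with the smallest p (circles, bars are 95% intervals), with the brightest other probe set of the same gene where there is one (diamonds). The diamonds of Tm9sf3, App, Caprin1 and Plekhb2 lie between 0.05 and 0.12, while their circles lie at 1.82 or above.

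The groups also differed in a measure of RNA quality. The control probe sets for the 3′ and 5′ ends of beta-actin and Gapdh lie farther apart when RNA is broken or labelling stops short. Their mean difference was 1.79 ± 0.28 in S and 1.12 ± 0.13 in congenic rats (log2, SD, n = 3), a difference of -0.67 with no overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow). S rat 2 had the highest value (2.10), and the first principal component, with 67.0% of the variance, put it at -40.1 against 15.6 to 22.3 for the congenic rats. With this difference as a term in limma's model, an alternative chosen after the data were seen, 0 probe sets passed, with 2292 below an unadjusted p of 0.05 in place of 7895 without the term, and 92.6% of the 1862 kept their sign. The 7 rises with a brighter, uncalled probe set then lay between -0.21 and 0.68, and the 11 named falls after Rbp4 between -1.18 and 0.11. The term itself separates the groups, so it can also widen the SE of a change. The median of the 156 rises of at least 2-fold shrank from 1.20 to 0.22. Fbln5 (from 0.58 ± 0.08 to 0.60 ± 0.17, SE) and Fcgr2b (from 0.75 ± 0.11 to 1.06 ± 0.21) did not shrink and still lost their calls. The 0 calls therefore do not show that RNA quality made all 1862 changes.

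**Figure D2:**
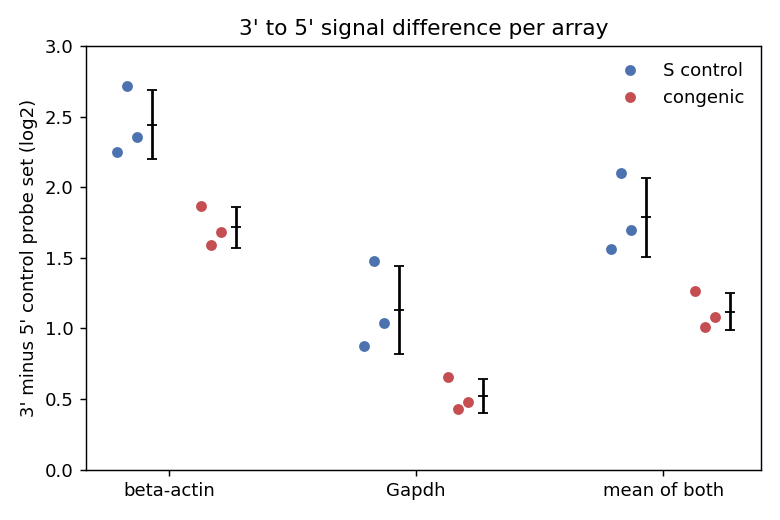
Difference between the 3′ and 5′ control probe sets (log2) of beta-actin, of Gapdh and of their mean, 1 point per array, with mean and SD as black bars. The means of the 3 S control arrays lie between 1.56 and 2.10 and those of the 3 congenic arrays between 1.01 and 1.26.

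Lists of tubular injury, matrix, fibroblast and mononuclear phagocyte genes were called higher in congenic rats at the preset correlation, and none at an estimated one. Of 22 measured tubular injury genes 10 rose and 12 did not pass, among them Havcr1, the kidney injury molecule (from 10.80 ± 0.22 to 11.61 ± 0.06, SD, n = 3), Lcn2, which encodes the secreted injury marker NGAL (log2 change 0.63), Clu, which encodes clusterin (0.61), and Spp1, which encodes osteopontin (0.48). A dimmer probe set of Clu, at a mean of 6.06, stood at -0.34 (adjusted p = 0.0340). The injury list shifted by a median of 0.32 (adjusted p = 1.04e-08, and adjusted p = 0.40 with an estimated correlation). Of 31 matrix and fibrosis genes 7 rose, including Tgfb1 (0.62), the protease inhibitor Timp1 (0.53) and the basement membrane collagen gene Col4a1 (0.45), with a list median of 0.23 (adjusted p = 1.04e-08, and adjusted p = 0.51 with an estimated correlation) that was 0.12 without S rat 1. Of 16 fibroblast and mural cell markers Lum, Fbln5 (0.58), Dcn (0.57) and Col1a1 (0.44) rose, while Col3a1, the most abundant, stood at 0.23 (adjusted p = 0.23); the list median was 0.33 (adjusted p = 7.81e-07, and adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, the calls were 13 up and 1 down for injury, 10 up for matrix and 7 up for fibroblasts.

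Of 19 macrophage and myeloid markers 5 rose, among them Fcgr2b, an inhibitory Fc receptor (0.75), C1qb, a complement subunit (0.46), Cd14 (0.39) and Lyz2, a lysozyme (0.35), while Ctss stood at 0.10 (adjusted p = 0.63). The macrophage median was 0.19 (adjusted p = 7.81e-07, and adjusted p = 0.63 with an estimated correlation), and 0.35 without S rat 2. Of 22 genes of antigen presentation 6 rose, with B2m (0.61) and the class II genes RT1-Ba (0.54) and RT1-Db1 (0.43) among them, and the median was 0.13 (adjusted p = 2.29e-06, and adjusted p = 0.51 with an estimated correlation). Of 36 cytokines and chemokines 6 rose, including the lymphoid chemokine Ccl21 (1.42), Tgfb1 and Spp1, with a median of 0.08 (adjusted p = 2.18e-05, and adjusted p = 0.51 with an estimated correlation) that was 0.049 without S rat 1. In the counts adjusted over the list alone, 6 macrophage, 7 antigen presentation and 8 cytokine genes passed, all higher. With the 3′ minus 5′ difference in the model the list medians were 0.50 for macrophages, 0.41 for matrix, 0.30 for antigen presentation, 0.30 for fibroblasts, 0.26 for injury and 0.16 for cytokines, and only the fibroblast list lost its call among these 6 (adjusted p = 0.25). With that term and an estimated correlation none of the 6 was called (adjusted p from 0.38 to 0.61).

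Proximal tubule transport moved in both directions. Of 16 markers of the early proximal tubule 4 rose, namely Slc5a12, Slc22a8, Slc5a2 and Slc4a4 (0.18 with the RNA quality term), and Slc22a12, the urate exchanger, fell (-0.43). The most abundant markers, Kap (-0.03) and Miox (-0.01), did not pass (adjusted p = 0.85 and adjusted p = 0.95). The list median was 0.26 (adjusted p = 0.00124, and adjusted p = 0.63 with an estimated correlation), 0.16 without S rat 2, and 0.03 with the RNA quality term (adjusted p = 0.88). Of 27 sodium and chloride transport genes 3 rose and 2 fell. Slc34a3, a phosphate transporter, rose by 1.53 and Stk39, a kinase that activates salt cotransporters, fell by 0.39. The median was 0.16 (adjusted p = 0.0287, and adjusted p = 0.63 with an estimated correlation). This call was lost under quantile normalization (adjusted p = 0.0606) and without S rat 2 (median 0.03, adjusted p = 0.11), S rat 3 (adjusted p = 0.0610) or congenic rat 1 (adjusted p = 0.0733). Without congenic rat 2 the median was 0.10, and with the RNA quality term the median was -0.04 and the list was called lower (adjusted p = 0.00572, and adjusted p = 0.73 with an estimated correlation). The counts adjusted over the list alone were 6 tubule markers higher and 1 lower, and 5 transport genes higher and 3 lower.

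**Figure D3:**
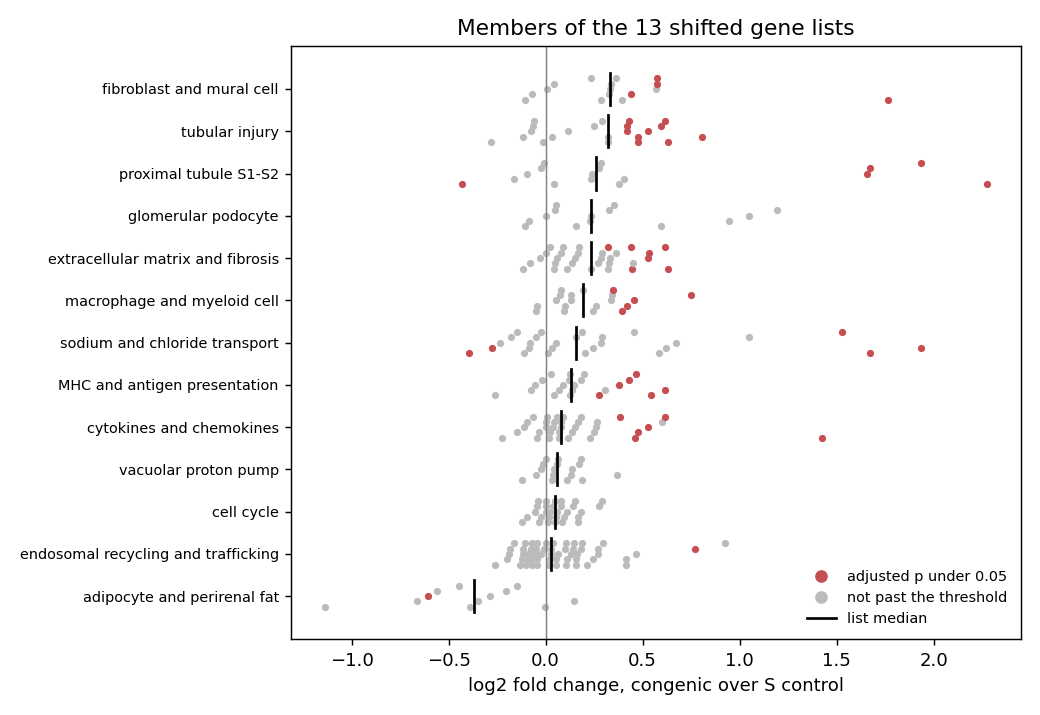
Log2 fold change, congenic over S control, of each measured member of the 13 shifted gene lists, 1 point per gene, in red where the adjusted p was under 0.05, with the list median as a black line. Medians run from 0.33 for fibroblast and mural cell markers down to -0.37 for adipocyte markers.

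Genes of endosomal recycling, the process named by the study, were nearly all below the threshold. Of 55 measured, Arf6, a small GTPase of membrane recycling, rose (0.77 ± 0.14 SE, adjusted p = 0.0267) and 54 did not pass, with Exoc5 at 0.93 (adjusted p = 0.0686) and Snx6 at 0.47 (adjusted p = 0.0603). Arf6 was at 0.21 ± 0.20 (SE) with the RNA quality term (limma, adjusted p = 0.91). The list median was 0.03 (adjusted p = 0.0332, and adjusted p = 0.63 with an estimated correlation), a call that was lost without S rat 2 (adjusted p = 0.0912), S rat 3 (adjusted p = 0.0959) or congenic rat 1 (adjusted p = 0.0961). The median turned to -0.0030 without S rat 3 and -0.0033 without congenic rat 1, and was 0.0080 without S rat 2, 0.06 without S rat 1 and 0.07 without congenic rat 2. With the most variable probe set of each gene in place of the brightest it was 0.16 (adjusted p = 0.00157). Of 28 genes of megalin-cubilin protein uptake 4 rose and 1 fell. Ctsb, a lysosomal protease, rose by 0.39, Folr1, a folate receptor, by 0.68 and Gulp1, an engulfment adaptor, by 0.30, and the list as a whole was not called (adjusted p = 0.0681). Ctsb was at 0.33, Folr1 at 0.20 and Gulp1 at 0.12 with the RNA quality term. At the brightest probe set of each gene none of 17 proton pump genes passed, with Atp6v0c at 0.37, Atp6v1g1 at 0.18 and Atp6v1b2 at 0.17. A dimmer probe set of Atp6v1b2 rose by 1.08 (adjusted p = 0.0449). The median of the pump list was 0.06 (adjusted p = 0.0193, and adjusted p = 0.63 with an estimated correlation). The call was lost without S rat 2 (adjusted p = 0.0592), S rat 3 (adjusted p = 0.0813) or congenic rat 1 (adjusted p = 0.0701). The medians with the RNA quality term were -0.02 for endosomal recycling and -0.01 for the pump. Adjusted over the list alone, 1 endosomal gene was higher, 4 uptake genes were higher and 2 lower, and 0 pump genes passed.

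Rffl, an endosomal ubiquitin ligase on chromosome 10 that is known from work on this congenic segment, was at 7.70 ± 0.05 in S and 7.88 ± 0.05 in congenic rats (log2, SD, n = 3). The log2 change of 0.19 is 1.14-fold, with a 95% interval of 1.03 to 1.26, and did not pass (adjusted p = 0.12). Its second probe set stood at 0.18 (adjusted p = 0.18). With the RNA quality term the first was at 0.29 and the second at -0.0073. Sequence differences between LEW and S under the probes were not analysed here. With array weights the first passed at adjusted p = 0.0495. Of 53 measured genes listed as near Rffl, 3 rose: Adap2, an Arf GTPase regulator (0.50), and the chemokine genes Ccl5 (0.53) and Ccl6 (0.46). Ccl5 and Ccl6 were measured genes 11 and 13 from Rffl in chromosome order, and none nearer to it passed. Adap2 was not among the 15 measured genes on either side. The limits of the congenic segment were not placed here. Values that missed the threshold were 0.38 for Evi2b (adjusted p = 0.0583), 0.22 for Tmem98, -0.15 for Mmp28, -0.18 for Aatf, -0.20 for Rhbdl3, -0.22 for Ccl9, -0.24 for Acaca and -0.29 for Slfn4. The list was not called (adjusted p = 0.54), and the same 3 passed in the count adjusted over the list alone. Of 1213 genes on chromosome 10, 50 were called (4.12%), against 628 of 12954 elsewhere (4.85%), an odds ratio of 0.84 with a 95% interval of 0.62 to 1.13 (Fisher's exact test, two-sided, p = 0.29). Tested in the same way outside the fixed design, the other chromosomes had adjusted p from 0.24 to 1 except chromosome 14, where 38 of 464 genes were called (8.19%, odds ratio 1.82, Fisher's exact test, adjusted p = 0.0255). Chromosome 18 came next, with 25 of 328 (7.62%, odds ratio 1.67, adjusted p = 0.24).

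**Figure D4:**
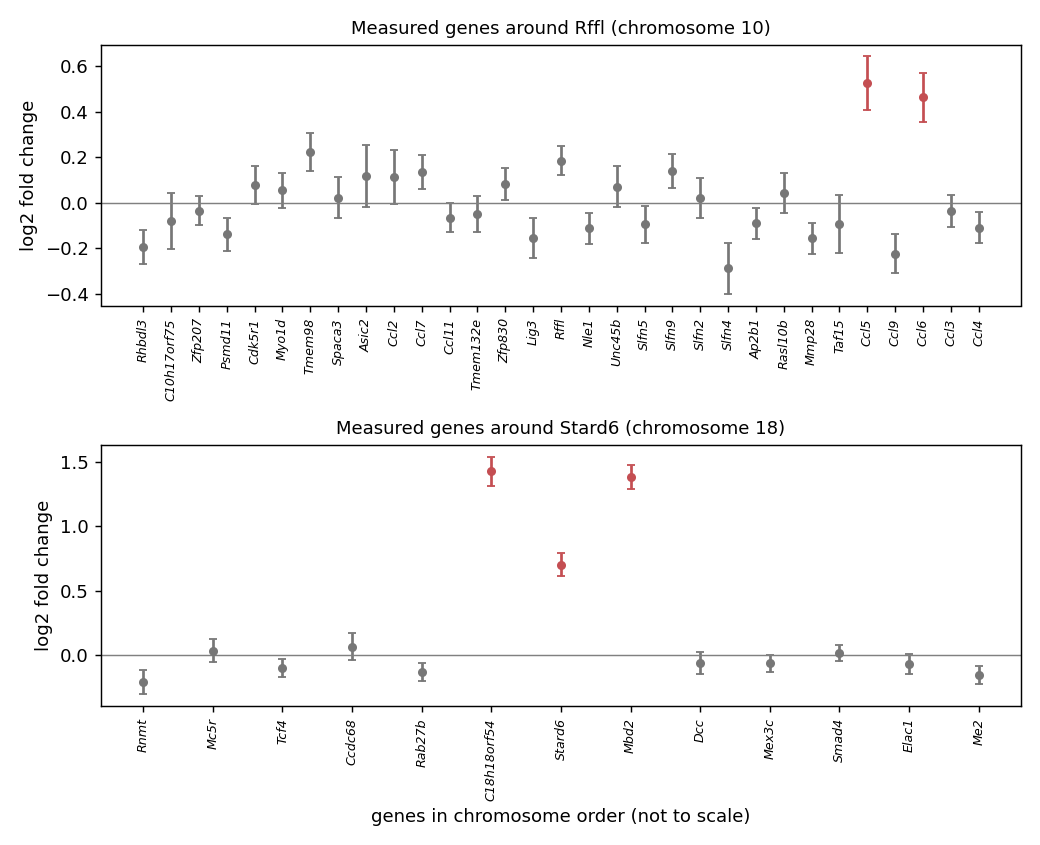
Log2 fold change, congenic over S control, with its SE, of measured genes in chromosome order around Rffl on chromosome 10 (top) and around Stard6 on chromosome 18 (bottom), in red where the adjusted p was under 0.05. Rffl lies at 0.19, and C18h18orf54, Stard6 and Mbd2 lie at 1.43, 0.70 and 1.38.

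Of 12 measured adipocyte markers Cidec, a lipid droplet protein, fell by 0.61 and 11 did not pass, with Ucp1 at -1.14 (adjusted p = 0.0507), Plin1 at -0.66 and Lpl at -0.21. The list median was -0.37 (adjusted p = 0.00866, and adjusted p = 0.63 with an estimated correlation). The call was lost without S rat 3 (median -0.23, adjusted p = 0.12), the median was -0.56 without S rat 1 and -0.62 with array weights, and the median was -0.06 with the RNA quality term (adjusted p = 0.29). None of 14 podocyte markers passed. Ptpro stood at 0.94 (adjusted p = 0.13), Nes at 0.60, Nphs1, which encodes nephrin, at 1.19 (S group SD 1.61, adjusted p = 0.29), Wt1 at 1.05 (S group SD 1.53, adjusted p = 0.33), Actn4 at 0.23 and Cd2ap, the most abundant, at -0.09. The podocyte median of 0.23 was called (adjusted p = 0.00866, and adjusted p = 0.63 with an estimated correlation), but not without congenic rat 1 (adjusted p = 0.0562), and it was 0.15 without S rat 2, 0.35 without S rat 1 and -0.10 with the RNA quality term. Nphs1 and Wt1 were at 5.67 and 5.05 in S rat 2, 6.90 and 6.89 in S rat 3, and 8.87 and 8.10 in S rat 1. None of 30 cell cycle genes passed either, with Cdc20 at 0.29, Kif11 at 0.27 and Pcna at 0.15. Their median was 0.05 (adjusted p = 0.0160, and adjusted p = 0.63 with an estimated correlation), 0.04 with the RNA quality term (adjusted p = 0.64), and the call was lost without S rat 1 (median 0.03, adjusted p = 0.0552) or congenic rat 2 (median -0.0051, adjusted p = 0.28). When adjusted over the list alone, 2 fat markers were lower and 0 podocyte or cell cycle genes passed.

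The other nephron segments, vessels, blood and neighbouring tissue were not called as lists by camera (adjusted p from 0.12 to 0.96), while single members were. The fry test called the thick ascending limb lower (adjusted p = 0.0412). Slc22a7 (-0.50) and Slco1a6 (-0.42) fell and Cyp2e1 (0.91) rose among 15 late proximal tubule markers. Ppp1r1a (-0.43) and Cldn16 (-0.35), a magnesium pore of the thick ascending limb, fell among 12 markers of that segment, with Ptger3 at -0.40 (adjusted p = 0.0568). A dimmer Ptger3 probe set went the other way and rose by 0.54 (adjusted p = 0.0283). S100g, a calcium-binding protein, fell (-0.42) among 11 distal tubule markers. There the brighter Trpv5 probe set stood at -0.21, while a dimmer one rose by 0.71 (adjusted p = 0.0171). Klk1, the tissue kallikrein, stood at 1.92 with an S group SD of 2.18 (adjusted p = 0.21). S rat 2 stood apart in this segment, with Klk1 at 7.25, the calcium buffer Calb1 at 9.38 and the thiazide-sensitive cotransporter Slc12a3 at 9.50. These markers were at 10.20, 12.73 and 11.73 in S rat 3, at 11.50, 13.51 and 12.42 in S rat 1, and at 11.49 or above, 13.46 or above and 12.21 or above in the congenic rats. Aqp4 (-0.59), a water channel, fell among 14 principal cell markers, with Elf5 at -0.51 and the brighter St6gal1 probe set at -0.31. Aqp4 was at -0.06 with the RNA quality term. Atp6v1c2 (-0.39) and Slc4a1 (-0.28), the chloride-bicarbonate exchanger, fell and Aqp6 (0.58) rose among 10 intercalated cell markers. Vwf (-0.54), the von Willebrand factor, fell among 15 endothelial markers, with Flt1 at 0.29 and Eng at 0.27. Cd4 (0.48) rose among 16 lymphocyte markers, with Ptprc at 0.32 and Cd5 at -0.18. Cd4 was at 0.09 and this Ptprc probe set at 0.58 with the RNA quality term. A dimmer Ptprc probe set rose by 0.84 (adjusted p = 0.00596). Slc4a1 was also the 1 member called of 6 blood markers, with Bpgm at -0.39 and Ahsp at -0.18, and Hsd3b1 (-0.57) the 1 member called of 10 adrenal markers, with Cyp21a1 at -0.31 and Pnmt at -0.15. Adjusted over the list alone, the calls were 2 up and 2 down for the late proximal tubule, 1 up and 3 down for the thick ascending limb, 1 down for the distal tubule, 4 down for principal cells, 2 up and 2 down for intercalated cells, 1 up and 1 down for endothelium, 2 up for lymphocytes, 2 down for blood and 1 down for the adrenal. With the RNA quality term 4 of these lists were called lower: distal tubule (adjusted p = 1.65e-05), intercalated cells (adjusted p = 0.000164), blood (adjusted p = 0.00323) and thick ascending limb (adjusted p = 0.00727). With an estimated correlation none was, with adjusted p from 0.51 to 0.66.

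Metabolic lists were not called (adjusted p from 0.13 to 0.96), with members that changed in both directions. Of 31 genes of xenobiotic metabolism, the fatty acid hydroxylase Cyp4a1 (0.75) and Cyp2e1 rose and Cyp2j4 (-0.56) was 1 of 2 that fell. Cyp4a1 was at 0.65 and Cyp2j4 at -0.06 with the RNA quality term. Cyp4a1 was also the only riser among 30 genes of fatty acid oxidation, where Acox2 stood at -0.42 and Pdk4 at -0.25. Ndufs4 (-0.30), a subunit of respiratory complex I, fell among 41 genes of oxidative phosphorylation, with Uqcrc2 at 0.54 and Ndufa2 at -0.24. Fdft1 (-0.33), a squalene synthase, fell among 20 genes of cholesterol synthesis, with Fdps at 0.34 and Idi1 at -0.28. Slc2a1 (-0.35), a glucose transporter, fell among 24 hypoxia response genes, with Adm at 0.44 and Eno1 at 0.31. The calls adjusted over the list alone were 3 up and 2 down for xenobiotic metabolism, 1 up and 1 down for fatty acid oxidation, 1 up and 3 down for cholesterol synthesis, 1 down for hypoxia and 0 for oxidative phosphorylation. Fatty acid oxidation was called lower with the RNA quality term (adjusted p = 0.00175, and adjusted p = 0.61 with an estimated correlation).

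Signalling lists were not called either (adjusted p from 0.0681 to 0.88). Agt (-0.35), which encodes angiotensinogen, fell and Gucy1a1 (0.48), a subunit of the nitric oxide receptor, rose among 24 genes of the renin-angiotensin and kallikrein systems, with Gucy1b1 at 0.34 (adjusted p = 0.0689). A dimmer Gucy1b1 probe set rose by 0.70 (adjusted p = 0.0235). Irf1 (0.36) and Irgm (0.39) rose among 35 interferon-stimulated genes, with Igtp at 0.24. Per3 (-0.37), a clock gene, fell among 20 circadian genes, with Bhlhe40 at 0.41 and Cry1 at -0.34. Nr4a1 (0.46) rose and Hspb8 (-0.52) and Fosl2 (-0.44) were the falls among 34 immediate early and heat shock genes. Cftr was the 1 member called of both 14 genes of the action potential, with Kcne1 at 0.54 and Ryr2 at -0.31, and 19 genes related to Rffl as a ubiquitin ligase, with Birc3 at 0.30. The calls adjusted over the list alone were 1 up and 1 down for the renin-angiotensin list, 2 up for interferon-stimulated genes, 1 up and 2 down for circadian genes, 2 up and 2 down for immediate early genes, and 1 down each for the action potential and ubiquitin ligase lists. The interferon list was called higher with the RNA quality term (adjusted p = 0.000343, and adjusted p = 0.73 with an estimated correlation).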

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

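Of 155 named probe sets, 96 passed the test in the data as reported. Where they had a value, which was 81 of the 96 with 1 probe set per gene and 94 with the dim filter, they kept their direction under each alternative except the RNA quality covariate, where Msn, Slc31a1 and LOC100910558 turned. All 96 lost significance in the unmoderated t-test, without S rat 3, without congenic rat 2 and with the RNA quality covariate, 92 did without congenic rat 3, 63 without congenic rat 1, 40 with the rat number as a replicate block and 20 without S rat 2. The cause was not tested unless stated.

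The count of changed probe sets was 658 with the replicate block (476 higher, 182 lower), 6077 with array weights (3128 higher, 2949 lower), 0 with the t-test (0 higher, 0 lower), and 0 with the RNA quality covariate (0 higher, 0 lower). With 1 probe set per gene, where fewer were tested, it was 666 (287 higher, 379 lower). It was 634 with a further limit of 1.5-fold and 4455 at an adjusted p under 0.1. Leaving out 1 rat gave 0 (without S rat 3) to 4752 (without S rat 1) changed, 0 to 2697 higher and 0 to 2055 lower. Without S rat 2 it was 968, of which 890 were among the 1862, without congenic rat 1 350 and without congenic rat 3 8. Same-numbered rats did not deviate together (correlations -0.01, -0.18 and -0.14), and 0 of the 6 rats correlated best with their own number. With 3 rats per group this cannot tell whether equal numbers mark a cage. The main test, fixed beforehand, did not pair the rats. Each cage held a congenic rat with an S rat, and the labels do not tie the numbers to cages, so an effect of the cage was not analysed here. The counts under quantile normalization, median centring, the dim filter, the intensity trend and robust eBayes stayed between 1832 and 2664.

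The number of shifted lists was 0 with an estimated correlation, 3 with fry, and 10 to 17 under the other alternatives. The RNA quality covariate left 13 lists called, but not the same 13. Of the main 13, 5 kept call and direction under it, 4 lost the call and 4 turned. With the RNA quality covariate the medians of podocyte (-0.10), endosomal recycling (-0.019), proton pump (-0.0077) and sodium transport (-0.040) lists turned. Leaving out 1 rat turned the endosomal median (-0.0030 without S rat 3, -0.0033 without congenic rat 1) and the cell cycle median (-0.0051 without congenic rat 2). With the most variable probe set per gene the medians of endosomal recycling (0.16), proton pump (0.14) and sodium transport (0.31) lists were larger, from 0.027, 0.060 and 0.16. With array weights the endosomal median was 0.059 and the adipocyte median -0.62, from -0.37. Quantile normalization gave 0.042 for endosomal recycling and 0.029 for the pump, and median centring 0.012 for endosomal recycling. The odds ratio of chromosome 10 turned to 1.00 under quantile normalization and 1.01 under median centring. It has no value with the t-test, with the RNA quality covariate, and without S rat 3, congenic rat 2 or congenic rat 3, where too few genes were called. The brighter probe set of Rffl ranged from 0.16 to 0.29, and passed with array weights alone (0.18, adjusted p = 0.0495), while its second probe set was at -0.0073 with the RNA quality covariate. The difference in RNA quality kept its direction under each alternative, from -0.51 to -0.78.

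Under quantile normalization Kap turned to 0.035. With array weights Kap turned to 0.0080 and Miox to 0.018. Leaving out 1 rat, Miox ranged from -0.029 to 0.0033 and Ahsp from -0.45 to 0.041. With the RNA quality covariate the following turned: Msn (-0.21), Slc31a1 (-0.26), LOC100910558 (0.11), Acaca (0.030), Ptpro (-0.10), Nes (-0.24), Ptger3 (0.013), Klk1 (-2.25), Calb1 (-2.70), Slc12a3 (-1.95), Nphs1 (-1.63), Wt1 (-1.78), Elf5 (0.078), Flt1 (-0.037), Pnmt (0.095), Exoc5 (-0.34), Atp6v0c (-0.13), Atp6v1g1 (-0.0085), Uqcrc2 (-0.18), Ndufa2 (0.054), Bhlhe40 (-0.0093), Kif11 (-0.11), Adm (-0.047), Eno1 (-0.015), Ryr2 (0.30), Kcne1 (-0.39), Birc3 (-0.021), Cd2ap (0.017), Kap (0.029) and Miox (0.030). That covariate was chosen after the data were seen. A different floor before taking logs was not run, since the values are already log2. Signal over background limits dim probe sets, for which no detection call was used here.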

Other observations

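The tests of RNA integrity and of tissue share, the covariate of RNA quality, the genes named here outside the lists and the test of gene order were chosen after the values were seen, and the split counts were set before their result. Among 32 genes of glutathione metabolism and targets of NRF2, a transcription factor that answers oxidative stress, 4 fell and 1 rose. Nqo1, a quinone reductase, fell by 0.52, Gsta3, a glutathione transferase, by 0.71 and Me1, malic enzyme, by 0.39. Osgin1, an oxidative stress response gene outside the list, fell by 0.46. The list was not called (adjusted p = 0.96), and 5 higher and 7 lower passed when adjusted over the list alone. With the RNA quality covariate its median was -0.11 and it was called lower (adjusted p = 0.000137, and adjusted p = 0.38 with an estimated correlation).

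Outside the lists, both probe sets of Igfbp3, which binds insulin-like growth factors, rose by 1.53 and 1.11, and Mfap4, a microfibril protein, rose by 0.94 ± 0.10 (SE). The values with the RNA quality covariate were 1.18, 0.95 and 0.95. The 9 spike-in control probe sets had a mean of 11.36 ± 0.04 in S and 11.21 ± 0.06 in congenic rats (SD, n = 3, exact permutation p = 0.1), and 8 of them were lower in congenic rats.

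The real grouping called 1862 probe sets, and the highest of the other splits of the 6 arrays into 3 and 3 called 0, so 1 of 10 splits reached the real count. With 10 splits the share cannot go under 0.05.

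The first pattern is the set of 156 probe sets at least 2-fold higher in congenic rats, and for 92 of them the gene has a brighter probe set, with a median log2 change of 0.047 (quartiles -0.05 and 0.17) against 1.18 for the named ones, which is consistent with differences in RNA integrity that reach some regions of a transcript more than others as a source of these rises. With the RNA quality covariate the median of the 156 went from 1.20 to 0.22 and the median SE from 0.23 to 0.26, and at the earlier SEs 20 of the 156 shrunken changes would have reached the p of the last call, so shrinkage alone was enough to end most of these calls, although the unshrunk changes at the new SEs, of which 99 would have reached that p, would not have passed adjustment in that fit either (0 of 156). Within the 3 S rats 96.8% of the 156 fell as the 3′ minus 5′ difference grew, against 45.1% of all probe sets (96.2% against 46.0% between S rats 1 and 3 alone), but markers such as Calb1 fell in the same order (13.51, 12.73 and 9.38 in S rats 1, 3 and 2), and within the congenic rats, which span a narrower range, the shares were 67.9% and 49.7%, which leaves that side undecided. Across all probe sets, which are not independent replicates, Pearson's r between the slope pooled within groups and the log2 change was -0.66, with -0.65 for the S slope and -0.24 for the congenic slope. S rat 2, the array farthest out on the first principal component, enters both the S slope and the S mean. That alone can make r negative, and no value of r under no change was computed. RNA quality and strain run together in these arrays, so a difference in tissue content and a strain difference in transcript ends, in splicing or in the sequence under the probes remain open and untested.

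The second pattern is the higher level of macrophage, antigen presentation and matrix lists, whose calls are lost with an estimated correlation (adjusted p = 0.63, adjusted p = 0.51 and adjusted p = 0.51). The shift that the slope on the 3′ minus 5′ difference within groups predicts has an upper 95% limit of 0.049 for macrophages, 0.0051 for antigen presentation and 0.11 for matrix. The observed mean shifts were 0.23, 0.18 and 0.23. For these 3 lists this argues against RNA integrity, as this slope measures it, as the whole cause. Among the other lists called higher, tubular injury also lay above its limit (0.28 against 0.22). The cytokine list did not (observed 0.1697, limit 0.172). Nor did the podocyte (0.36, 1.79), early proximal tubule (0.54, 1.34), sodium transport (0.31, 1.14), endosomal recycling (0.07, 0.305), proton pump (0.078, 0.315) and cell cycle (0.057, 0.327) lists. For lists below their limit the slope leaves RNA integrity open as the whole cause. For the fibroblast list the slope predicted a rise of 0.19 (95% interval 0.092 to 0.29), against an observed 0.38. These slopes rest on 3 residual degrees of freedom. S rat 2 had the highest 3′ minus 5′ difference (2.10) and also the lowest Calb1 (9.38), so the slopes may not measure RNA integrity alone. A lower share of tubule in the congenic pieces was taken to raise fibroblast and endothelial markers alike. Endothelial markers stood at a mean of -0.02, and fibroblast markers shifted by 0.39 more (95% interval 0.23 to 0.56). With the RNA quality covariate they shifted by 0.19 more (95% interval 0.022 to 0.35). This goes against an even rise of both, but it covers no macrophage or antigen presentation gene. It does not show which part of the kidney each piece held, so a difference in tissue share stays open. Only a lower tubule share in the congenic pieces was tested, although the early proximal tubule list was called higher in congenic rats. Calb1 was at 9.38 and 12.73 in S rats 2 and 3 and Slc12a3 at 9.50 and 11.73. The congenic rats were at 13.46 or above and 12.21 or above, and S rat 1 at 13.51 and 12.42. A lower tubule share in the S pieces was not tested. The candidate explanation that the strains differ in phagocytes and matrix stays a hypothesis, since cell counts were not analysed here.

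The third pattern is a run of 3 neighbouring genes on chromosome 18 of the GRCr8 assembly, C18h18orf54, Stard6 and Mbd2, which rose by 1.43, 0.70 and 1.38, while Rab27b (-0.13) and Dcc (-0.06) on either side did not pass. Their mean shift was 1.17, and 1.21 with the RNA quality covariate (95% interval 0.47 to 1.96), which argues against RNA integrity as its source. In 11.8% of 10000 random gene orders at least 1 run of 3 or more neighbouring risers occurred. By that count chance placement of the 300 risers stays possible. The count takes each called riser alike, whatever its size or p, so it does not weigh how strong this run is. In limma's test the adjusted p of C18h18orf54, Stard6 and Mbd2 were 0.00596, 0.0171 and 0.00511. The last value was the smallest that any probe set reached. A strain difference at this site, outside the named congenic segment, may be another source, and genotypes were not analysed here. The only other run was of 4 class II genes on chromosome 20, RT1-Da, RT1-Db1, RT1-Ba and RT1-Bb (0.38, 0.43, 0.54 and 0.47), and 2 or more runs occurred in 0.62% of the orders.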
